A study of Mus musculus with 4 samples.

How the data were processed

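Gene expression was measured on 4 two-colour Agilent mouse arrays. Each array carried RNA of 1 mtB6 and 1 mtBALB cybrid culture of the same replicate number, so that each array is a direct comparison of a pair. Cybrids are cells in which the mitochondria of a donor are combined with the nucleus of a recipient line that has lost its own mitochondrial DNA. Both lines are fibroblasts named LMEB3, and per the labels they carry mitochondria of C57BL/6J (mtB6, the control) or BALB/cJ (mtBALB) mice. The replicates are described as biological replicates and the study's title speaks of independent clones. The dyes were swapped: on replicates 1 and 3 the mtB6 RNA was labelled with Cy5 and the mtBALB RNA with Cy3, and on replicates 2 and 4 the reverse. Total RNA was extracted with silica columns and labelled with the standard two-colour protocol, in which 1 mix of control transcripts goes with Cy3 and another with Cy5, per the labels' protocols.

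The values used are the authors' deposited log ratios, 1 per spot and array, taken as log2. The submitters' processing notes name limma without a version. Background correction, normalization and filters are not given in the sources used here, and scanner intensities were not used here, so that signal over background is unknown and the number of arrays limits the precision. The base of the logarithm is not stated either. Groups of spots with no gene listed had replicated ratios as far from 0 as -2.45, which argues against base 10, and base 2 is the scale limma works on. The medians over all spots were -9.76e-04, -0.0033, 0.0051 and -0.0030 on replicates 1 to 4, so each array was centred before deposit.

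Whether the ratios had been turned to 1 direction between the lines was read from control-like spots. Of 171 spots with no gene listed and an absolute log2 ratio of at least 0.6 on all 4 arrays, 163 changed sign with the dye orientation, 8 had another pattern and 0 had 1 sign throughout. Control transcripts that follow the dye must alternate in sign after turning, so the ratios were taken as already turned. The correlation between arrays of opposite orientation, the fallback fixed for arrays without such controls, was below 0 over all spots and by itself would have read as ratios not turned. That reading was run as an alternative. Which line is in the numerator is not settled by the labels or the values. Signed values are therefore given as the positive or negative side of the deposited ratio, and no line is named as the higher.

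Of 45220 spots, 33653 were listed with 1 gene in the platform annotation, 56 with several and 11511 with none. Spots with several genes or none were not named. Symbols were updated through gene IDs in a RefSeq table of GRCm38.p6, where 18966 of 19088 genes matched. That assembly served for names and for the order of genes, and no coordinates are given because the sources used here name no build. The spots of a gene were averaged, dim ones included, so that a mean can hide spots that disagree. There were no missing values, so that requiring 3 measured arrays in place of 4 changes nothing. Between 53.7% and 56.0% of the spots of an array had a value that at least 3 spots of the array shared exactly, as ratios of low whole-number signals would. Such spots are called dim here, although their brightness was not measured. There were 24286 to 25320 per array, with a median absolute log2 ratio of 0.10 to 0.12 against 0.20 to 0.27 for other spots, and 9774 genes had a spot that was dim on no array.

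The line difference was tested in limma 3.58.1 under R 4.3.3 with lmFit and eBayes on all 4 arrays, with the mean ratio and a dye effect per gene as terms, which leaves 2 residual degrees of freedom per gene. P-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. Gene lists were tested with camera at its preset correlation of 0.01, adjusted over the lists, with a correlation estimated for each list as an alternative, and with fry beside it. Of 34 lists fixed before the data were examined, 33 had at least 5 measured genes and were tested. They cover mitochondrial gene groups, stress responses, metabolism, matrix, adhesion, inflammation, proliferation and markers of other cells. The tests, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule for the case of no gene past the threshold takes the 8 genes of smallest p on each side of 0, leaving out clone names, and the 2 members of smallest p of each list, as values. The genes encoded in mitochondrial DNA are always given. Values per gene are means over arrays with the SD (n = 4). The SD includes the dye effect, which the fit takes out before its p-value.

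The fit was tested on simulated data for 19088 genes and 4 arrays, with dye effects and variances as fitted to the real genes and 200 genes changed. At a log2 size of 0.5 it called 0% of the changed genes at the adjusted threshold and 90.0% at an unadjusted p under 0.05. At a size of 1 it called 82.0% at the adjusted threshold, with 7 unchanged genes called beside them, and at a size of 2 it called 97.0%, with 15. A simulated list of 30 genes shifted by 0.25 passed camera and 0 of the unshifted lists did. Genes varied independently in these simulations, which the real genes do not.

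Alternatives were a model with no dye term, arrays centred on their median, arrays scaled to the same spread, array weights, robust eBayes, leaving out each replicate, leaving out the 25% of genes with the smallest mean absolute ratio, every spot on its own, the median of a gene's spots, an adjusted p under 0.10 and a minimum absolute log2 ratio of 1. Lists were also tested on ranks. Spots that were not dim, ratios taken as not turned, and the sign of replicate 3 turned were added after the data were seen.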

Results

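The arrays compared the transcripts of mouse cybrid fibroblasts that carry mitochondria of C57BL/6J mice (mtB6, the control) with those of cybrids that carry mitochondria of BALB/cJ mice (mtBALB). There were 4 arrays, each with 1 culture of either line, and 2 arrays in each dye orientation. The comparison asks how nuclear and mitochondrial gene expression differ between cells that differ in their mitochondrial genotype. Because the deposited ratios do not say which line is in the numerator, signs below give the side of the ratio and not the line with more transcript.

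No single gene separated the lines across the pairs. Of 19088 genes, 0 passed an adjusted p of 0.05 in limma, and the smallest adjusted p was 0.9997. At an unadjusted p under 0.05 there were 694 genes, 303 on the positive and 391 on the negative side, where 954 are expected by chance. The 95% interval of a gene's log2 ratio had a median half-width of 0.20, or 0.25 for genes with a spot that was dim on no array. In simulated arrays with variances as fitted to all genes and 200 genes changed, 82.0% of genes with a log2 difference of 1 were recovered and 0% of those with 0.5. In that setting differences of the smaller size did not reach the adjusted threshold with 4 arrays. The share recovered depends on how many genes change, and other numbers were not simulated.

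The genes of smallest p on the positive side included carriers of nuclear import and a pore protein. The importins Kpna2 and Kpna4 had mean log2 ratios of 0.46 ± 0.10 and 0.34 ± 0.02 (SD, n = 4), and the nucleoporin Nup205 had 0.38 ± 0.20. The spots of Kpna4 differed in size, with means of 0.29, 0.53 and 0.21. The value of Nup205 averages never dim spots at 0.71 and 0.51 and a spot dim on 4 arrays at -0.10. Elovl6, an elongase of fatty acids, had 0.42 ± 0.12, and Pgam5, a phosphatase of mitochondria, had 0.35 ± 0.05. The splicing factor Isy1 had 0.47 ± 0.12 and Cip2a, an inhibitor of protein phosphatase 2A, had 0.43 ± 0.28. All of these were positive on each of the 4 arrays. The receptor phosphatase Ptprf had 0.50 ± 0.49, with -0.03 on replicate 2. On the negative side, Naip5 and Nod2, sensors of bacterial products, had -0.75 ± 0.47 and -0.52 ± 0.22. The circadian repressor Ciart had -0.52 ± 0.26 and the antiproliferative gene Btg1 had -0.42 ± 0.17. Anxa13 had -0.58 ± 0.28, Tmem229b had -0.60 ± 0.36, the chloride cotransporter Slc12a5 had -0.79 ± 0.49 and Slc23a3 had -0.51 ± 0.34. These 8 genes were negative on each array. None of the genes named here passed the adjusted threshold.

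**Figure D1:**
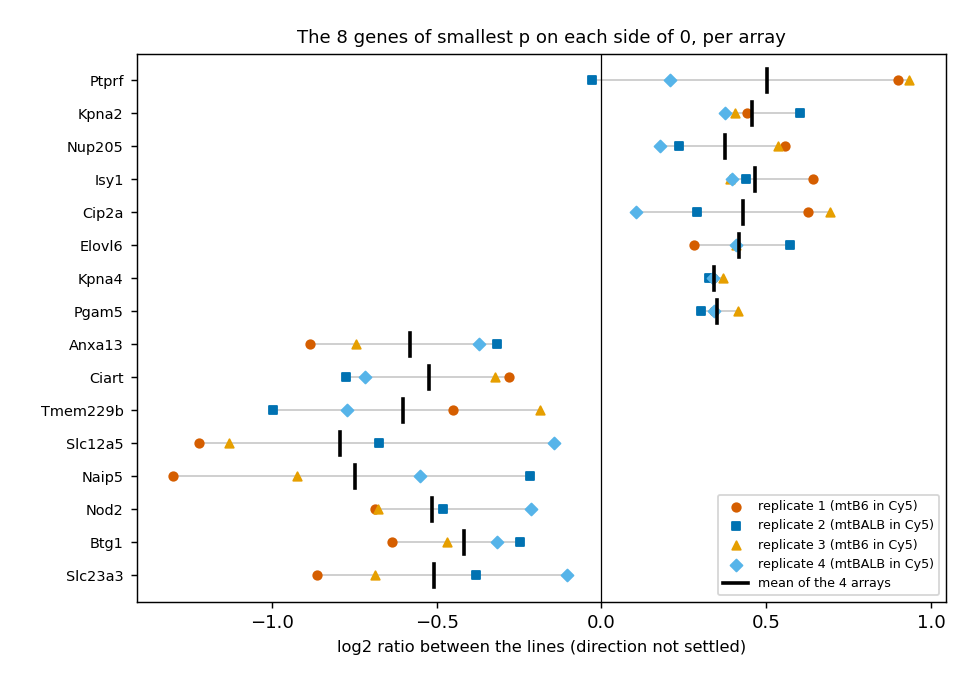
Log2 ratio on each array (x axis, symbols by replicate and dye orientation, black bars the mean of the 4 arrays) of the 8 genes with the smallest p on either side of 0 (y axis). Kpna4, averaged over 3 spots, stays close to its mean of 0.34 on all arrays, while Slc12a5 ranges from -1.22 to -0.14.

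Lipid synthesis genes lay together on the positive side. Of 27 genes of cholesterol and fatty acid synthesis, 26 had a positive mean and 9 had an unadjusted p under 0.05. The mean of the list was 0.74 on replicate 1, 0.28 on replicate 2, 0.40 on replicate 3 and -0.12 on replicate 4. The list passed camera with an adjusted p = 1.45e-14, but not with an estimated correlation (adjusted p = 0.675 with an estimated correlation). Elovl6 and the desaturase Scd1 had the smallest p. Scd1 had a mean of 0.33 ± 0.61, with 0.77 and 0.94 on replicates 1 and 3 and -0.22 and -0.17 on replicates 2 and 4. No member passed the threshold over all genes or adjusted over the list alone.

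The mean of the cell cycle genes lay on the positive side in all 4 pairs. Of 47 genes, 42 had a positive mean and 10 were positive on all 4 arrays. The list means were 0.39, 0.10, 0.07 and 0.09 on replicates 1 to 4. The mean over arrays was 0.16, and 0.08 without replicate 1. Camera gave an adjusted p = 7.94e-12 and, with an estimated correlation, an adjusted p = 0.675. The cyclin Ccne2 had 0.31 ± 0.23 and the replication licensing factor Mcm2 had 0.37 ± 0.25. Genes of the tricarboxylic acid cycle also passed camera on the positive side (adjusted p = 0.0177, and adjusted p = 0.826 with an estimated correlation). Their list mean was 0.31 on replicate 3 and between -0.06 and 0.05 on the others, and the adjusted p was 0.925 without replicate 3 and 0.304 without replicate 4. The mean over arrays was 0.08, and 0.15, -0.00 and 0.05 without replicates 1, 3 and 4. Sucla2 had 0.21 ± 0.14 and Aco1 had 0.15 ± 0.19.

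Cytosolic ribosomal protein genes lay on the negative side by their mean, with 60 of 68 members below 0 (camera adjusted p = 3.64e-09, and adjusted p = 0.675 with an estimated correlation). Their list means followed the dye orientation, at 0.14 and 0.09 on replicates 1 and 3 and -0.35 and -0.31 on replicates 2 and 4. Only 1 member was negative on all 4 arrays. Rps23, whose spot was dim on at least 1 array, and Rps13 had -0.22 ± 0.52 and -0.19 ± 0.25.

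Genes of the integrated stress response that ATF4 controls, inflammatory chemokines and cytokines, and leukocyte markers passed camera on the negative side. For the stress response, 21 of 29 genes had a negative mean and the adjusted p was 0.0075, or an adjusted p = 0.826 with an estimated correlation. Its list means were -0.20 and -0.21 on replicates 1 and 4 and -0.01 and -0.00 on replicates 2 and 3, and the mean over arrays of -0.11 became -0.06 without either replicate 1 or 4. Ppp1r15a, which ends the response, had -0.45 ± 0.40, and Ddit4, an inhibitor of mTOR, had -0.43 ± 0.27. For the 41 chemokine and cytokine genes the adjusted p was 0.0315, or an adjusted p = 0.675 with an estimated correlation. The chemokine Ccl5 had -0.90 ± 0.46, with -1.42, -0.99, -0.30 and -0.90 on replicates 1 to 4, and the NF-kappaB subunit Nfkb2 had -0.20 ± 0.23. Of 17 leukocyte markers, only 4 had a spot that was dim on no array. The list had an adjusted p = 0.0335, or an adjusted p = 0.675 with an estimated correlation, and Lyz2, the lysozyme of macrophages, had -0.32 ± 0.19. The value of Lyz2 averages a never dim spot at -0.69 and a spot dim on 4 arrays at 0.04. Leaving out single replicates ended the camera calls of these 3 lists: replicates 1 or 4 for the stress response (adjusted p = 0.61 and 0.28), 2 or 3 for the chemokines (0.107 and 0.109), and 1, 2 or 3 for the leukocyte markers (0.311, 0.148 and 0.109).

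Lists of nuclear genes for mitochondrial proteins, apart from the tricarboxylic acid cycle, did not pass camera with all 4 arrays. The 77 genes of the respiratory chain and ATP synthase had a list mean of 0.00 (array means between -0.16 and 0.13; camera adjusted p = 0.928). The 78 mitochondrial ribosomal protein genes had 0.01 (adjusted p = 0.81), the 34 mitochondrial tRNA synthetases and translation factors had -0.01 (adjusted p = 0.966), and the 30 genes of mitochondrial biogenesis and DNA maintenance had -0.04 (adjusted p = 0.281). The 32 genes of fusion, fission and import had 0.04 (adjusted p = 0.0615), with 23 members positive and array means of 0.09, 0.02, 0.02 and 0.06. That list passed with no dye term (adjusted p = 0.0249), on ranks (0.0459) and without replicate 2 (0.0335), and the mitochondrial ribosomal list passed without replicate 3 (0.0187). Single members of smallest p were Ndufa13 at -0.28 ± 0.28 and Cox5b at -0.29 ± 0.23, subunits of complexes I and IV, and for the mitochondrial ribosome Mrpl9 at 0.26 ± 0.14 and Mrps9 at -0.17 ± 0.14. The methionyl-tRNA synthetase Mars2 had -0.33 ± 0.25 and the elongation factor Gfm1 had 0.15 ± 0.25. Gfm1 followed the dye orientation, with 0.35, -0.08, 0.39 and -0.06 on replicates 1 to 4. The deacetylase Sirt3 had -0.33 ± 0.23, the coactivator Ppargc1b had -0.24 ± 0.17, and the import proteins Tomm22 and Timm8b had 0.20 ± 0.18 and -0.34 ± 0.52. Among 14 mitochondrial chaperones and proteases, Hspe1, the small partner of the mitochondrial chaperonin, had -0.33 ± 0.06 and was between -0.38 and -0.26 on every array. It was the 1 gene of any list that passed in limma when adjusted over the list alone (adjusted p = 0.0435), and it did not pass over all genes. That adjustment was made within each of 34 lists and not across them, so that 1 such pass may be chance. The protease Afg3l2 had -0.14 ± 0.18.

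**Figure D2:**
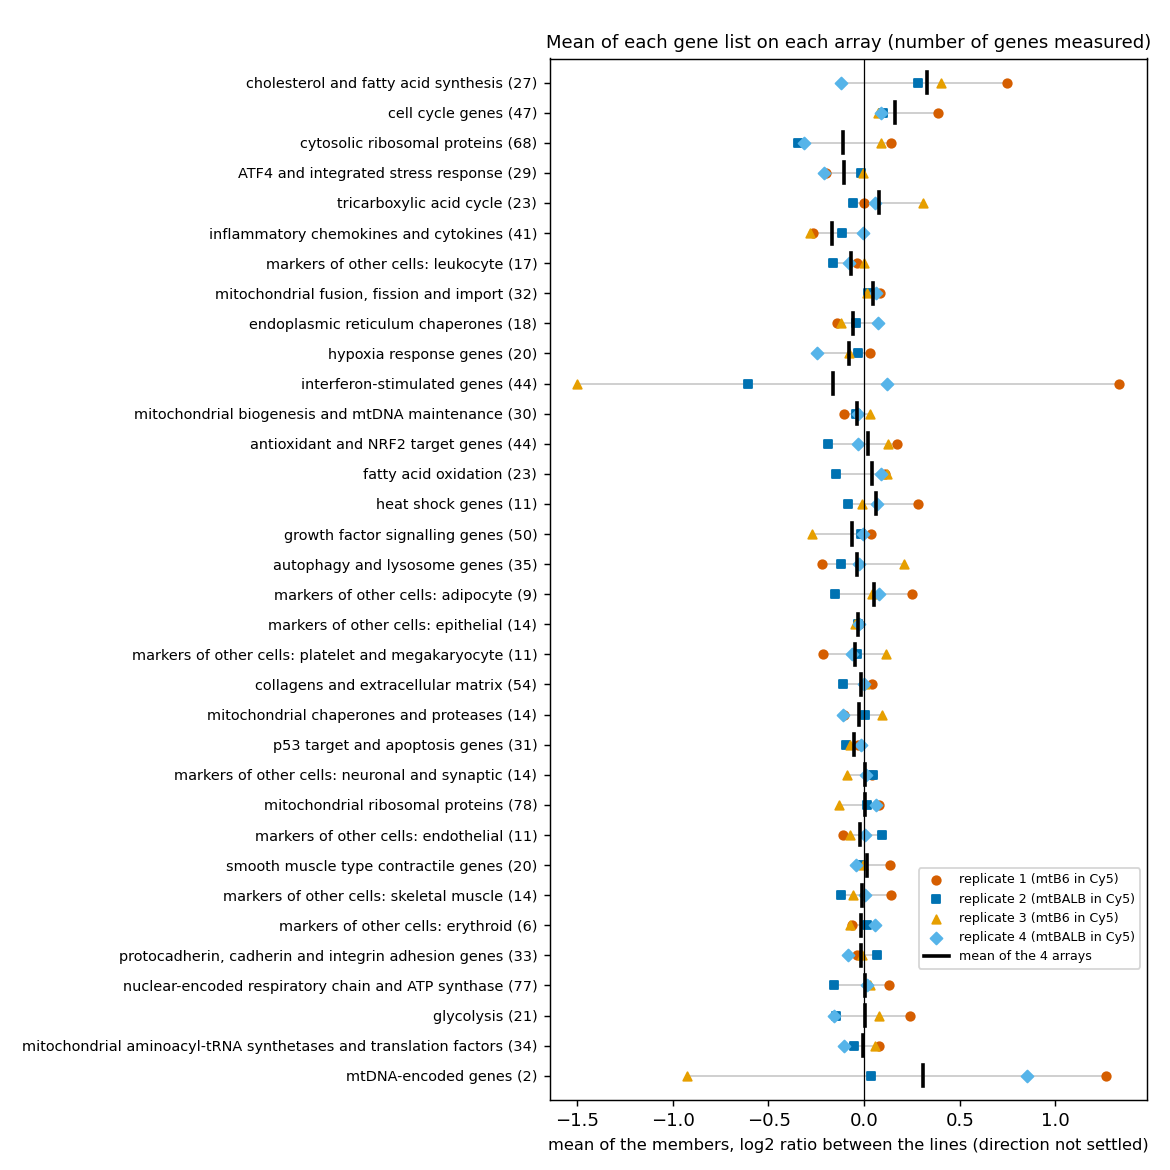
Mean log2 ratio of each gene list (y axis, number of measured genes in parentheses) on each array (x axis, symbols by replicate and dye orientation, black bars the mean of the 4 arrays). The mean of the cell cycle list is above 0 on all 4 arrays, while that of the interferon-stimulated list ranges from 1.33 on replicate 1 to -1.50 on replicate 3.

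The widest differences between cultures were in interferon-stimulated genes, and they had no shared direction. Their list means were 1.33 on replicate 1, -0.61 on replicate 2, -1.50 on replicate 3 and 0.12 on replicate 4. The list did not pass camera over all 4 arrays (adjusted p = 0.281, and adjusted p = 0.938 with an estimated correlation). Without replicate 1 it passed on the negative side (adjusted p = 7.54e-31), and without replicate 3 on the positive side (adjusted p = 1.28e-17). Of 44 members, 42 were above 0 on replicate 1 and below 0 on replicate 3. The 2 members the rule names, Ifit2 and Parp14, had means of -0.28 ± 0.36 and -0.27 ± 0.56. Among members chosen after their values were seen, the antiviral gene Ifit1 had 3.00, -1.45, -4.13 and -0.00 on replicates 1 to 4. The ubiquitin-like modifier Isg15 had 2.28, -1.37, -2.51 and 0.33.

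The genes encoded in mitochondrial DNA that the arrays measured also spread widely. COX2, a subunit of cytochrome c oxidase, had 1.36, 0.22, -1.22 and 0.90 on replicates 1 to 4, a mean of 0.31 ± 1.12. ND4L, a subunit of complex I, had 1.17, -0.15, -0.63 and 0.81, a mean of 0.30 ± 0.83. Neither spot had a value that 3 or more spots shared on any array. Neither mean differed from 0 by more than the spread between pairs, and both means turned negative without replicate 1. With 2 members the group had no set test.

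**Figure D3:**
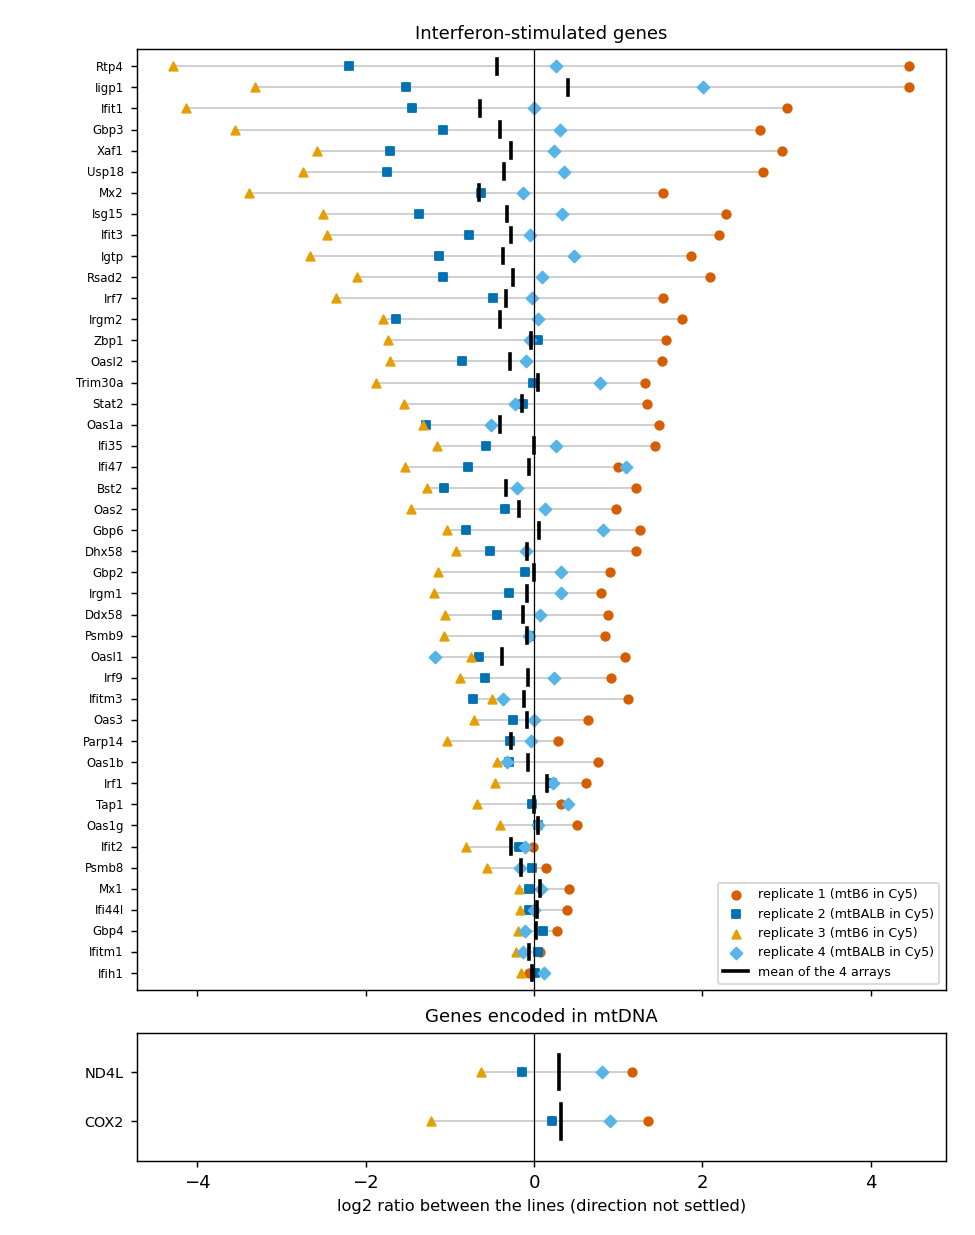
Log2 ratio on each array (x axis, symbols by replicate and dye orientation, black bars the mean of the 4 arrays) of 44 interferon-stimulated genes and the 2 measured genes of mitochondrial DNA (y axis). Ifit1 lies at 3.00 on replicate 1 and -4.13 on replicate 3, and COX2 at 1.36 and -1.22.

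Other stress and metabolic lists did not pass camera with all 4 arrays. The adjusted p was 0.281 for antioxidant genes controlled by NRF2, 0.346 for heat shock genes, 0.0617 for endoplasmic reticulum chaperones, 0.966 for glycolysis, 0.217 for hypoxia response genes, 0.342 for fatty acid oxidation, 0.757 for p53 target and apoptosis genes and 0.542 for autophagy and lysosome genes. Leaving out 1 replicate brought 5 of these lists past camera. The autophagy list passed on the positive side without replicate 1 (adjusted p = 0.0279) and on the negative side without replicate 3 (6.40e-05). Its means were -0.22, -0.12, 0.21 and -0.03 on replicates 1 to 4. The NRF2, hypoxia and fatty acid oxidation lists passed without replicate 2 (0.0118, 0.0150 and 0.0150) and the endoplasmic reticulum list without replicate 4 (0.0293). In fatty acid oxidation, Eci2 and the medium-chain dehydrogenase Acadm had 0.33 ± 0.16 and 0.37 ± 0.18, positive on each array. Hmox1, the inducible heme oxygenase, had -0.27 ± 0.15 and the sulfiredoxin Srxn1 had 0.25 ± 0.24. The cochaperone Dnaja1 had 0.25 ± 0.21 and Hsp90aa1 had 0.24 ± 0.36, while Pdia6 and Creld2 of the endoplasmic reticulum had -0.19 ± 0.13 and -0.19 ± 0.14. The spots of Pdia6 disagreed, with means of -0.61, -0.15, -0.05 and 0.05. In glycolysis, Pfkp had -0.21 ± 0.31 and Ldha had 0.14 ± 0.45, and of the hypoxia genes Mxi1 had -0.23 ± 0.25. Ldha followed the dye orientation, with 0.59, -0.29, 0.46 and -0.22 on replicates 1 to 4. The spots of Pfkp disagreed, with means of -0.51, -0.06 and -0.07. Cytochrome c (Cycs) had 0.45 ± 0.36 and was positive on each array, and the caspase Casp8 had -0.19 ± 0.13. The autophagy genes Sqstm1 and Gabarapl1 had -0.28 ± 0.41 and -0.14 ± 0.08.

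Matrix, contractile, adhesion and growth factor genes had adjusted p-values of 0.588, 0.878, 0.882 and 0.459, and the growth factor list passed without replicate 1 (0.0349). Collagen Col1a1 had 1.11 ± 1.05, with 2.51, -0.02, 0.84 and 1.12 on replicates 1 to 4 over 12 spots, and Col16a1 had -0.35 ± 0.12. The value of Col16a1 averages a never dim spot at -0.63 and a spot dim on 3 arrays at -0.08. The contractile list's Vcl and Mylk had 0.26 ± 0.17 and -0.18 ± 0.16, and the integrins Itgb5 and Itga6 had -0.22 ± 0.19 and -0.18 ± 0.13. The receptor Pdgfrb had -0.47 ± 0.27, negative on each array, and the immediate early gene Egr1 had -0.98 ± 1.07, or -0.35 without replicate 3.

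Markers of adipocytes, epithelium, platelets, neurons, endothelium, skeletal muscle and erythroid cells had adjusted p-values of 0.542, 0.542, 0.588, 0.772, 0.855, 0.88 and 0.88. Every spot of the markers named here was dim on at least 1 array, except for 1 spot of Syn1 and the spots of Tyrobp and Myod1. Plin1 and Adipoq had 0.20 ± 0.11 and -0.07 ± 0.17, Krt8 and Cdh1 had -0.17 ± 0.28 and -0.08 ± 0.11, and Pf4 and Gp1bb had -0.48 ± 0.57 and 0.12 ± 0.12. Gap43 and Syn1 had 0.10 ± 0.16 and -0.14 ± 0.34, Vwf and Kdr had -0.21 ± 0.24 and -0.06 ± 0.14, and Klf1 and Alas2 had -0.13 ± 0.09 and 0.06 ± 0.01. The leukocyte marker Tyrobp had -0.11 ± 0.07. The muscle actin Acta1 had 0.35 ± 0.72. The muscle gene Myod1 followed the dye orientation, with 1.34, -1.31, 0.67 and -1.31 on replicates 1 to 4.

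The arrays shared little of their ratios across genes, which are not independent replicates. Over genes, Pearson's r between arrays was between -0.19 and 0.05 for the 6 pairs of arrays, and -0.19 for replicates 1 and 3, which have the same dye orientation. Signs agreed on all 4 arrays in 9.02% of genes and alternated with the dye orientation in 21.3%, where 12.5% is expected of either with independent signs. By fry, which asks whether a list's genes move 1 way on balance, 0 of 33 lists passed, with a smallest adjusted p of 0.363. All 7 lists that passed camera did so only with the preset correlation. For the chemokine and leukocyte lists the estimated correlation lay below the preset, so that a higher correlation is not the reason. An exact sign-flip test over 4 arrays cannot give a p under 0.125.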

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

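The tests of dye, of turning, of an exchange on replicate 3, of a line difference in all pairs and of sign patterns for genes were chosen after the results were seen, and those of sign patterns for lists and of leaving out replicate 1 before.

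A few results have 1 array far from the others by Dixon's criterion for 4 samples. The list mean of cell cycle genes was 0.386 on replicate 1, far from the other 3 arrays, and that of fatty acid oxidation was -0.146 on replicate 2. Lyz2 had -0.613 on replicate 2. Chance marks about 1 in 20 groups, and these are 2 of 34 list means and 1 of 82 genes. Outside the named genes, 163 spots with no gene listed had large ratios whose sign alternated with the dye orientation.

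The first pattern is that arrays of opposite dye orientation correlated below 0 over all spots (r from -0.24 to -0.17). If the deposited ratios had not been turned, the alternating part would be the line difference and would agree between different spots of a gene, but its correlation between spots was 0.105, lower by 0.135 than the weakest of the other 3 parts (the difference is -0.135, with a bootstrap interval of -0.185 to -0.0820). A dye-dependent background of low signals remains a candidate explanation: the mean r was -0.271 over dim spots and -0.0274 over spots that were never dim, a difference of -0.244. Over dim spots alone the alternating part had the highest correlation between spots, 0.0825 against 0.0176 to 0.0331 for the others. No biological explanation was tested for this pattern, because a line difference does not follow the dye.

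The second pattern is the opposite position of interferon-stimulated genes on replicates 1 and 3. Dye bias is argued against by replicates 2 and 4, which share an orientation and were not part of this observation but whose list means differed by 0.727, over 2 SE of the members (an SE that takes them as independent), and a wrongly turned replicate 3 by 166 of 171 control-like spots having the sign its recorded orientation gives. A difference between the lines of 1 sign in all pairs was not decided. With the cultures as labelled, the list means of 1.33 on replicate 1 and -0.61 on replicate 2 lay on opposite sides. Replicate 1 is, however, part of this observation. An exchange of replicate 3 alone would leave these means on opposite sides, while an exchange of replicate 1 or of replicate 2 alone would not. Exchanges of replicates 1 or 2 were not tested. The test on replicates 2 and 4 could not decide, with replicate 4 at 0.12 within 2 SE of 0. A line difference smaller than the spread between pairs (SD over arrays 1.20) cannot be told apart. An exchange of both cultures of replicate 3 cannot be told apart from other causes: without these genes replicate 3 correlated negatively with all others, at most -0.0636 with replicate 4, but the other replicates do not all correlate positively with each other. A state of single cultures or clones that may drive the interferon response stays open and untested.

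The third pattern is the position of the cholesterol and cell cycle lists on the positive side. Replicate 1 as the only cause predicted that the lists would not pass camera without it. At its preset correlation camera then gave an adjusted p of 1.45e-06 for the cholesterol list and 0.0019 for the cell cycle list. This cannot decide, because the preset of 0.01 takes genes as nearly independent, while the estimated correlations were 0.36 and 0.21. Without replicate 1 camera also passed the interferon-stimulated list, whose array means lay on both sides of 0. The means of the cholesterol and cell cycle lists fell from 0.33 to 0.24 and from 0.16 to 0.08, and stayed above 0. A dye effect equal on all arrays cancels from these means, which cover 2 arrays of each orientation. One that differs between arrays cannot be told apart. The means by orientation were 0.23 and 0.0921 for cell cycle genes, with all 4 arrays above 0. For the cholesterol list they were 0.57 and 0.0796, with replicate 4 below 0. For cell cycle genes this test restates what was observed and is no separate support. With 7 sign patterns of the 4 arrays that can be fitted beside the dye, no share under 0.05 is possible: 7 lists passed in the real pattern and at most 7 in another, and 2 patterns, the real one included, gave as many. A line difference stays open, and no list passed with an estimated correlation.

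For single genes the same 7 sign patterns gave 694 genes at an unadjusted p under 0.05 in the real pattern and at most 1557 in another, with as many or more in 5 patterns, the real one included, which is too few patterns for a share under 0.05. The patterns with most genes were those that set replicate 3 against replicate 1, and the cause was not tested. Replicates 1 and 3 also had the widest ratios over genes, with SDs of 0.32 and 0.30 against 0.27 and 0.23 on replicates 2 and 4. If the cultures of replicate 3 had been exchanged, the pattern with 1557 genes would itself be the line difference.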

How the results depend on the processing

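Taking only spots that were not dim, taking the ratios as not turned and turning replicate 3 were chosen after the data were seen. The count of genes past the adjusted threshold in limma was 0 in all 17 alternatives. At an unadjusted p under 0.05 it was 694 in the main fit, 443 without the 25% of genes of smallest ratio, 1188 with every spot on its own, 270 with spots that were not dim, 1714 with ratios taken as not turned and 1341 with replicate 3 turned. The first 3 alternatives tested fewer or more genes or spots. Taking the ratios as not turned exchanges the mean ratio and the dye effect of the main fit. Its 1714 genes are therefore those whose dye effect had an unadjusted p under 0.05 in the main fit. The lists below for that setting likewise test that dye effect. The cause of the count with replicate 3 turned was not tested. Leaving out 1 replicate gave 426 to 1579, and such fits rest on 1 residual degree of freedom, from the pair of arrays that share an orientation. The number of lists past camera fell from 7 to 0 with an estimated correlation, and was 6 to 9 otherwise. With ratios taken as not turned, which would make them mtBALB over mtB6, 6 lists passed and all lay on the negative side, against 3 positive and 4 negative in the main fit. Among them were the cholesterol list (adjusted p = 3.98e-05), the ribosomal list, glycolysis and the respiratory chain, while cell cycle and tricarboxylic acid cycle genes did not pass (0.0508 and 0.199). With an estimated correlation the adjusted p in camera was 0.826 for the stress response and the tricarboxylic acid cycle. It was 0.675 for the cholesterol, cell cycle, ribosomal, chemokine and leukocyte lists. The estimated correlation was -0.021 for the chemokines and -0.060 for the leukocyte markers, below the preset of 0.01. Their unadjusted p in camera still rose, from 0.0057 to 0.082 and from 0.0071 to 0.101. A higher correlation is therefore not why these lists no longer passed. For the other lists that had passed it was between 0.052 and 0.36, and the cause was not tested. Leaving out 1 replicate gave adjusted p-values of 1.48e-04 to 0.61 for the stress response, 8.94e-05 to 0.925 for the tricarboxylic acid cycle, 0.0202 to 0.109 for the chemokines and 0.0438 to 0.311 for the leukocyte markers; the cholesterol, cell cycle and ribosomal lists passed each time.

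Named genes kept their sign in 813 of 819 alternative values. The others came from leaving out 1 replicate, where ND4L ranged from -0.15 to 0.75, COX2 from -0.33 to 0.96, Parp14 from -0.60 to 0.057, Syn1 from -0.32 to 0.037, Acta1 from -0.012 to 0.71 and Myod1 from -0.32 to 0.015. Leaving out 1 replicate moved the mean of 32 of the 82 named genes by over 1.5 times, such as Egr1 (-1.60 to -0.35), Ifit2 (-0.48 to -0.077), Timm8b (-0.51 to -0.16) and Hsp90aa1 (0.10 to 0.38). Col1a1 (0.69 to 1.53), Cycs (0.26 to 0.64) and Pdgfrb (-0.63 to -0.30) were also among them. Lists not past camera in the main fit kept that in 214 of 227 values, 26 of them with an estimated correlation. The others were fusion, fission and import (0.0249 with no dye term, 0.0459 on ranks) and, from leaving out 1 replicate, that list and those of interferon-stimulated, mitochondrial ribosomal, autophagy, growth factor, NRF2, hypoxia, fatty acid oxidation and endoplasmic reticulum chaperone genes. Requiring 3 measured arrays could not be run, because there were no missing values. Each array pairs same-numbered cultures, so the main fit is paired and no further pairing was possible. Signal over background is unknown.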

Other observations

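The genes of this part, apart from Egr1, were chosen after their values were seen. Among 19088 genes, 12 had a mean log2 ratio of at least 1 in size and 6 of these had 1 sign on all 4 arrays, all negative. Cox6a2, the muscle type of a cytochrome c oxidase subunit, had -1.48, -1.75, -1.22 and -0.66 on replicates 1 to 4, a mean of -1.28 ± 0.47 (SD, n = 4) from 1 spot. Ncf4, a subunit of the phagocyte NADPH oxidase, had -2.57, -3.32, -0.15 and -1.13. Cd28, a T-cell costimulatory receptor, had -3.04, -0.50, -0.13 and -2.14 as the mean of 11 spots. Mamdc2 had -2.77, -0.92, -0.17 and -1.58. Serpinb1a had -1.18, -2.13, -0.975 and -0.04, and Slc47a1 had -0.38, -0.34, -3.075 and -0.46. Their means were -1.08 and -1.06, and that of Slc47a1 rested mostly on replicate 3.

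Among immediate early genes, on replicates 1 to 4, Fos had 0.40, -0.69, -1.77 and 0.33, Egr1 had 0.04, -0.996, -2.46 and -0.49, and Dusp1 had 0.74, 0.08, -2.37 and 0.60. Jun had 0.24, 0.28, -1.41 and 0.03, and Ccn1 had -0.04, -0.57, -2.66 and 0.52. The fixed list of growth factor genes had a mean of -0.27 on replicate 3 and did not pass camera (adjusted p = 0.459). Within the cholesterol list, Idi1 had 1.55, 1.06, 1.18 and -0.25 on replicates 1 to 4, Cyp51 had 1.46, 0.58, 0.88 and -0.20, and Hmgcs1 had 1.11, 0.49, 0.53 and -0.10.

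Ratios of genes near each other on a chromosome were correlated. This was taken over 9752 genes with a spot that was dim on no array, with ratios past 1 in size set to 1 in size. Ratios of genes 20 apart in chromosome order had correlations of 0.0829, 0.125, 0.0775 and 0.0721 on replicates 1 to 4. In 1000 random orders of the genes they were at most 0.0389. Medians of single chromosomes went as low as -0.30 on replicate 1 and as high as 0.29 on replicate 3, where random orders gave at most 0.11 on either. What gives rise to this was not tested.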
